A study of Mus musculus with 2 samples.

How the data were processed

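Single-nucleus ATAC-seq was performed on striatum of wild-type mouse embryos at embryonic day 14.5. In this assay a transposase cuts and tags accessible DNA in isolated nuclei, and each nucleus receives its own barcode in a droplet. Per the labels, nuclei were isolated and libraries were made with 10x Genomics Chromium reagents, and the strain background was C57BL/6J and CD1. There were 2 libraries in 1 group. The labels do not say that the libraries came from separate embryos, and no comparison between groups exists in the design.

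Per the submitters' processing notes, the genome build was mm10 and Cell Ranger ATAC 1.2.0 and Signac were used. The notes give these names without role or order. Which tool called the peaks, and whether the libraries were pooled first, is not given in the sources used here. How doublets, droplets with more than 1 nucleus, were treated is not given either, and no doublet step could be run on a list of peaks. The deposited peak list is 1 set for the whole series. Each of its 87174 lines holds only the position of a peak, with no count, score or sample. Read depth, number of nuclei and agreement between the libraries are therefore unknown here, and intervals printed below cover counting of peaks or genes only. Whether starts are counted from 0 or from 1 is not stated, so positions are printed as deposited and can be off by 1 base.

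Genes came from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 names. Of its 49997 gene entries, 402 were left out: those on unplaced or alternate scaffolds, those on no main chromosome, and repeated symbols. Scaffold entries carried a chromosome name but restarted its positions, which was noticed after first results had been seen. The same results with these genes kept are among the alternatives. This left 49595 genes, of which 21774 were protein-coding. All peaks lay on chromosomes 1 to 19, X and Y.

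The table gives each gene's span but no strand, exon or transcript, and no genome sequence was used here. The promoter window planned before the data were examined was therefore replaced by a window of 1000 bp to either side of either end of an annotated gene. A peak overlapping such a window by at least 1 bp is called a gene-end peak, and any other peak a distal peak. Gene-end peaks thus include peaks at the far ends of genes and miss promoters inside a gene span. Random placement used the span between the first and last peak or gene of each chromosome, since unsequenced stretches were not known. The planned analyses that need sequence, motif occurrence in distal peaks and co-occurrence of DLX and MEIS motifs, were not run.

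Shares were given exact 95% binomial confidence intervals (Clopper-Pearson) and compared with 100 random placements of the same peaks on the same chromosomes. Widths of gene-end and distal peaks were compared by a two-sided permutation test of the difference of medians with 100000 resamples. Peaks are not independent replicates, so this p-value describes the 1 peak set.

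A locus is a protein-coding gene span with 50 kb on each side. Fixed before the data were examined were 18 gene lists, of striatal, other brain and non-brain cell types, with housekeeping, Hox and olfactory receptor genes as further groups. All 222 genes listed by name were found in the table. For each list the mean number of distal peaks per locus, and the share of genes with a gene-end peak, were placed among 10000 random lists of protein-coding genes of the same size, matched on 10 classes of gene length. A list beyond the 2.5 or 97.5 percentile was said to lie outside the range of random lists. This describes 1 peak set and carries no p-value, and about 0.9 of 18 lists would lie outside by chance. Loci overlap where genes are neighbours, so 1 peak can count for several genes. The 200 loci richest in distal peaks were compared with the lists by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 lists.

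Broad peaks were analysed after the data had been seen: a gene was counted when a peak of the broadest 1% reached within 1000 bp of its span. Gene families and a list of 39 transcription factors of other organs were also added later.

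The list test was tested on simulated data. Peaks were placed at random along the chromosomes and counted at the loci of the 21774 protein-coding genes, and peaks were added at 20 sets of 200 genes. Of 1000 lists of 15 genes per fold size, 2.9% lay above the range without added peaks, 57.6% at 1.5-fold, 96.1% at 2-fold and 100% at 3-fold. A list of 15 genes with an excess near 1.5-fold was thus missed often in the simulation. Random placement spreads peaks more evenly than the deposited peaks lie, and gene-end peaks were not set apart. The rates for the deposited peaks can therefore differ from these.

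Genes were named by a rule set before the data were examined: Dlx1, Dlx2, Meis2 and Six3, the 10 loci with most distal peaks, up to 3 members of each described list with most distal peaks and up to 2 with no peak at all, and the 3 longest genes with no peak in their locus. Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen. Alternatives changed the gene-end window, the flank, the way peaks were given to genes, the pool and matching of random lists, and the peak set. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.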

Results

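Accessible chromatin was profiled in nuclei of the striatum of wild-type mouse embryos at E14.5, an embryonic age at which the ganglionic eminences supply the striatum with new neurons. The 2 libraries belong to 1 group, and their deposited result is 1 shared list of 87174 peaks, that is, regions called accessible. The peaks covered 77.7 Mb of mm10. Their median width was 565 bp (quartiles 363 and 1135 bp), and the range ran from 1 to 64767 bp. Neighbouring peaks lay at least 501 bp apart, and whether closer regions were joined into 1 peak is not given. A broad peak therefore need not be accessible throughout, and any joining would lower peak counts at dense loci. The list holds positions alone, so read depth is unknown and there is no replicate error for any value below. The series' title concerns Meis2 expression that depends on Dlx1 and Dlx2 in neuronal fate. With 1 genotype, stage and tissue, the comparisons set gene loci against other loci of the same peak set.

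Broad peaks lay over the whole of Dlx1 and Dlx2 and over both ends of Meis2, the genes named in the title. A single peak of 25417 bp on chromosome 2, from 71523172 to 71548589, covered both Dlx1 (gene span 71528113 to 71533981) and Dlx2 (71543408 to 71546754), which encode homeodomain transcription factors of ganglionic eminence progenitors. It also reached the end of the neighbouring gene Metap1d. At Meis2, which encodes a TALE homeodomain factor of striatal projection neurons, a peak of 21116 bp from 116055514 to 116076630 on chromosome 2 covered one end of the gene (span 115861264 to 116067537), and a peak of 9523 bp from 115852026 to 115861549 covered the other end. Six3, which encodes a homeodomain factor of the developing forebrain, was overlapped by a peak of 12055 bp on chromosome 17, from 85612160 to 85624215, and a second peak of 2249 bp from 85624809, which together covered 95.3% of its span (85613608 to 85626191).

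The number of peaks differed between these loci, as did gene length, from 206274 bp at Meis2 to 3347 bp at Dlx2. The Meis2 locus held 34 peaks, 32 of which overlapped the gene span and 32 of which were distal. The Dlx1 locus held 12 peaks and the Dlx2 locus 11, most of them shared, and the 25417 bp peak was the only one to overlap either gene. At the Six3 locus 14 peaks were present, 12 of them distal. Relative to the mean of genes in the same length class, distal peaks were 2.45 times as many at Meis2. The same ratio was 3.39 at Dlx1, 3.42 at Dlx2 and 3.29 at Six3. Most distal peaks of the Dlx1 and Dlx2 loci, those between 71483498 and 71520168, lay inside the neighbouring gene Metap1d (71453281 to 71525194). Among all peaks the one over Dlx1 and Dlx2 ranked 4 by width and the one over the Meis2 end ranked 9. Dlx5 and Dlx6, chosen after their values were seen, lay together under a peak of 25330 bp on chromosome 6, from 6857785 to 6883115, which ranked 5. These loci were described and not tested.

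**Figure D1:**
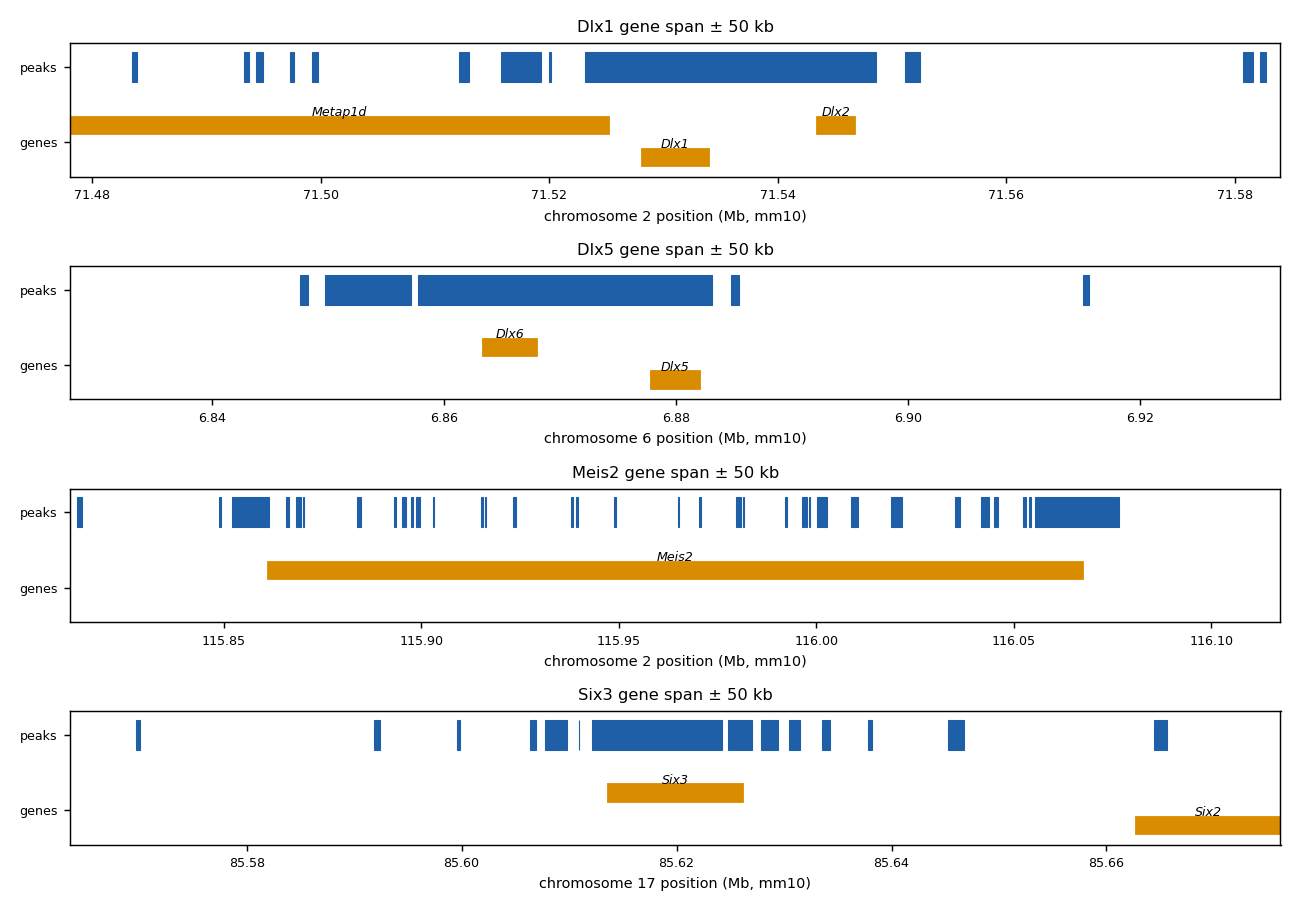
Peaks (blue) and protein-coding gene spans (orange) at the Dlx1, Dlx5, Meis2 and Six3 loci, each drawn to its own scale with 50 kb on either side of the gene and mm10 position in Mb on the horizontal axis. Single peaks of 25417 and 25330 bp covered the Dlx1 and Dlx2 pair and the Dlx6 and Dlx5 pair. Meis2, a far longer gene of 206274 bp, held 32 peaks that overlapped its span.

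Whether genes of striatal and other cell types had more distal peaks than other genes of similar length was then examined. Loci of striatal projection neuron transcription factors held a mean of 20.7 distal peaks, 2.45 times the mean of random lists (8.44), and all 20 loci had at least 3. Foxp1, a forkhead factor, had 55 distal peaks and Ebf1, a factor of the direct-pathway lineage, 40. Ganglionic eminence progenitor regulators had a mean of 6.47 distal peaks against 3.12 in random lists (2.07 times), with 11 at Dlx1, 10 at Dlx2 and 9 at Olig1. Most of those at Dlx1 and Dlx2 are shared and lay inside Metap1d. Radial glia and neural progenitor genes had 1.86 times the random mean, led by Nfia with 53 distal peaks, Nfib with 27 and the Notch receptor gene Notch1 with 15. Pan-neuronal genes had 2.38 times the random mean, led by the neurexin gene Nrxn3 with 67, the splicing regulator Rbfox3 with 52 and the ankyrin gene Ank3 with 44. Many of these genes are very long. With 50 length classes in place of 10, the pan-neuronal ratio fell to 1.77 (random mean 13.4, percentile 99.5) and that of striatal factors to 2.06, both above the range.

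In the medial ganglionic eminence and interneuron list the mean was 1.74 times the random mean, with 35 distal peaks at Sox6, 25 at Zeb2 and 16 at Erbb4. The 39 Hox genes had 3.04 times the random mean, with 14 distal peaks each at Hoxb3, Hoxb5 and Hoxb6, which are neighbours and share them. Microglia genes had 1.74 times the random mean, and their highest values, 15 at C1qb, 15 at C1qc and 14 at C1qa, also came from neighbours. These 7 of 18 lists lay above the range of random lists, at percentiles of 99.995 for ganglionic eminence regulators, 100 for striatal factors, 99.5 for radial glia, 99.99 for pan-neuronal genes, 98.4 for interneuron genes, 100 for Hox genes and 97.6 for microglia genes. The microglia list fell inside the range under 6 of 11 alternatives, at the lowest to 1.16 times and the 72.3 percentile with a flank of 10 kb, and the interneuron list under 4 of 11, at the lowest to 1.36 times when gene-end peaks were counted too. The ganglionic eminence list fell inside it under that setting (1.41 times, percentile 96.8), and the Hox list (1.07 times) with each peak given to its nearest gene end. That assignment raised the ratio to 6.13 for ganglionic eminence regulators, 4.19 for striatal factors, 4.90 for radial glia genes and 3.87 for interneuron genes, so the size of these ratios depends on how peaks are given to genes.

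Markers of mature striatal projection neurons lay inside the range, with 1.52 times the random mean (percentile 96.7). Their loci ranged from 1 distal peak to 37 at Pde10a, a striatal phosphodiesterase gene, followed by 16 at Arpp21 and 15 at Chrm4. Caudal ganglionic eminence genes had 1.67 times the random mean (percentile 94.8), with 14 distal peaks at Reln, 11 at Nr2f2 and 9 at Npas1, and cortical excitatory lineage genes had 1.44 times (percentile 94.3), with 13 at Neurod2, 12 at Emx1 and 9 at Neurog1. Oligodendrocyte lineage genes had 1.47 times, with 20 at Mbp, 19 at Cspg4 and 7 at Myrf. Skeletal muscle genes had 1.46 times, with 24 at Pax7, a factor also used in the neural tube, 11 at Tnnt3, 10 at Ryr1 and no peak of any kind at the Myh1 locus. Housekeeping genes had 1.26 times, with 11 each at Actb and Rplp0 and 8 at Ywhaz. Caudal ganglionic eminence genes rose above the range with each peak given to its nearest gene end (4.46 times) or matching on neighbours (2.03 times), cortical genes under 3 alternatives (1.64 to 1.89 times) and mature striatal markers with a flank of 100 kb (percentile 98.4). With 50 length classes, oligodendrocyte genes (1.63 times) and skeletal muscle genes (1.58 times) also lay above it.

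Genes of the remaining cell types were close to random lists. Erythroid genes had 1.22 times the random mean, with 10 distal peaks each at Epor and Slc4a1 and 8 at Tal1. Choroid plexus and ciliated cell genes had 1.15 times, with 10 at Otx2, 9 at Aqp1 and 8 at Dnah5. Liver genes had 0.944 times, with 7 at Fgb, 6 at Fga and 6 at Hnf4a, and endothelial and mural genes had 0.930 times, with 14 at Erg, 13 at Pdgfrb and 12 at Pecam1. All 4 lists lay inside the range. The 1105 olfactory receptor genes were the only list below it, with a mean of 0.288 distal peaks against 1.25, or 0.230 times. These genes lie in clusters, and the ratio was 0.477 with 1 member per 200 kb and 0.141 with each peak given to its nearest gene end, both below the range. Of them 848 had no peak of any kind in their locus (76.7%), Olfr1 and Olfr1002 among them, while Olfr70 and Olfr71 had 10 distal peaks each and Olfr1513 had 6.

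**Figure D2:**
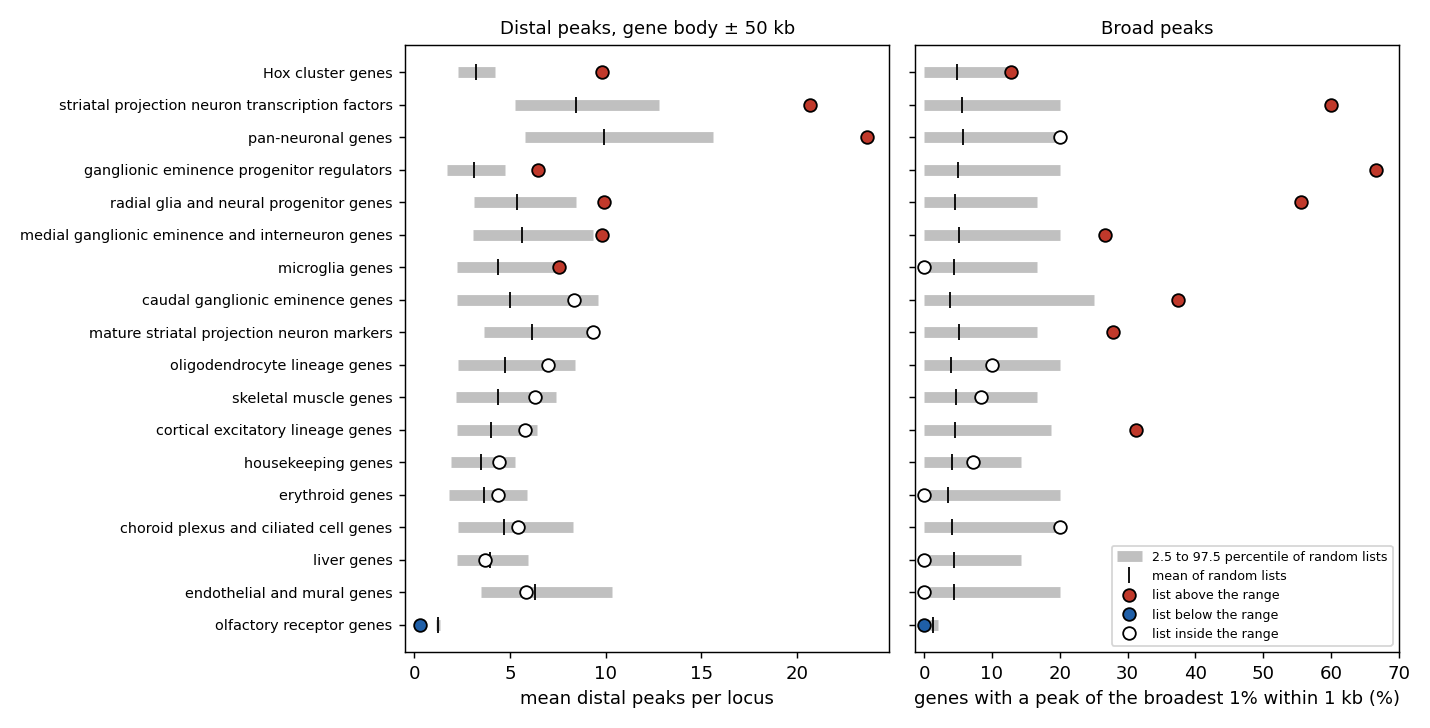
For each of the 18 gene lists, the mean number of distal peaks per locus (left) and the percentage of genes with a peak of the broadest 1% within 1 kb (right) are shown as circles, filled where the list lay above (red) or below (blue) the range of random lists. Grey bars give the central 95% of 10000 random lists matched on gene length and ticks give their mean. Striatal transcription factors reached 20.7 distal peaks and 60% of genes, against random means of 8.44 and 5.65%.

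Gene-end peaks were present at nearly all genes of several brain lists and at few liver or olfactory receptor genes. All 15 ganglionic eminence regulators, all 15 interneuron genes, all 16 cortical lineage genes and all 39 Hox genes had a gene-end peak, as did 17 of 18 mature striatal markers, 17 of 18 radial glia genes and 13 of 14 housekeeping genes. In contrast only 4 of 14 liver genes (28.6%) and 9 of 1105 olfactory receptor genes (0.814%) had one. Among liver genes Fga had a gene-end peak, whereas Fgb and Hnf4a had none. Striatal transcription factors had gene-end peaks at 19 of 20 genes, and Foxp1 and Ebf1 were among them. Microglia genes had them at 7 of 12 and erythroid genes at 5 of 10.

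Compared with random lists of similar length, the first 7 lists lay above the range and liver and olfactory receptor genes below it. Of these, mature striatal markers (percentile 98.3), radial glia genes (98.6) and housekeeping genes (98.15) lay on the edge. Their shares equalled the upper limit of the random lists, and ties were split in the percentile. Random means were 62.0% for ganglionic eminence regulators, 70.8% for liver genes and 21.1% for olfactory receptor genes. Striatal transcription factors (percentile 96.9) and pan-neuronal genes (15 of 15, percentile 97.4) lay inside the range, as did the other 7 lists. With a gene-end window of 2500 bp, mature striatal markers and housekeeping genes fell inside the range, and with peaks wider than the median striatal transcription factors (percentile 98.6) and pan-neuronal genes (98.5) lay above it.

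Very broad peaks, examined after the data had been seen, were frequent at regulators of forebrain development. The broadest 1% comprised 872 peaks wider than 4479 bp, and 3.95% of protein-coding genes had one within 1 kb of their span. Among ganglionic eminence regulators 10 of 15 genes did, Dlx1 and Dlx2 included, as did 12 of 20 striatal transcription factors, Meis2, Six3 and Foxp1 included, and 10 of 18 radial glia genes, Notch1 and Nfib included. Pax6 (17055 bp) and Sox2 (16381 bp), both progenitor factors, and Mn1 (21855 bp) were among genes with very wide peaks, chosen after their values were seen. Shares were lower in caudal ganglionic eminence genes (3 of 8), cortical lineage genes (5 of 16), mature striatal markers (5 of 18) and interneuron genes (4 of 15). The mature striatal markers with such a peak were Slc32a1, Gad1, Gad2, Chrm4 and, just over the cut, Pde10a (4593 bp). Drd1, Drd2, Adora2a, Penk, Pdyn and Tac1 were among those without one. No microglia, endothelial, erythroid or liver gene had such a peak, which lay inside the range of random lists for each of them.

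The 7 brain lists just named, and Hox genes with 5 of 39 (percentile 97.535, on the edge), lay above the range of random lists, and olfactory receptor genes with 0 of 1105 lay below it. With 1 member per 200 kb the Hox and olfactory receptor lists fell inside it (percentiles 41.2 and 5.5). Random means were 4.96% for ganglionic eminence regulators, 5.65% for striatal factors and 4.53% for radial glia genes. With the broadest 5% of peaks, mature striatal markers (1.75 times) and caudal ganglionic eminence genes (2.06 times) fell inside the range, whereas pan-neuronal genes (2.92 times) and housekeeping genes (3.15 times, percentile 99.86) lay above it. The ratio fell from 13.4 to 5.76 for ganglionic eminence regulators, from 10.6 to 2.98 for striatal factors and from 12.3 to 3.87 for radial glia genes. These 3 lists stayed above the range. Neighbouring genes such as Dlx1 and Dlx2 share 1 peak.

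The 10 loci richest in distal peaks belonged to long genes, of 248828 bp (Dnah8) to 1612235 bp (Nrxn3). Auts2, a gene of neuronal development spanning 1105888 bp on chromosome 5, had 130 distal peaks, followed by Gse1 with 87, the RNA-binding protein gene Msi2 with 84, the axonemal dynein gene Dnah8 with 80 and Btbd9 with 78. Zfhx3 had 77, the adhesion molecule genes Ntm and Tenm4 71 each, Camta1 69 and Nrxn3 67. Dnah8 and Btbd9 are neighbours on chromosome 17 and share peaks. The longest protein-coding genes with no peak in their locus were Skint5 (521613 bp) and Skint6 (482358 bp), members of an epithelial immunoglobulin gene family, and Cnbd1 (354571 bp), all on chromosome 4.

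Of the 1366 genes on any list, 15 were among the 200 richest loci, or 1.10% against 0.919% of all protein-coding genes (odds ratio 1.21, two-sided Fisher's exact test, p = 0.462). By the same exact test, pan-neuronal genes gave 6 of 15 (odds ratio 74.1, adjusted p = 4.68e-08) and striatal transcription factors 6 of 20 (odds ratio 47.6, adjusted p = 1.75e-07), and olfactory receptor genes gave 0 of 1105 (adjusted p = 0.000351). The median locus held 3 distal peaks. The ranking was not adjusted for gene length, and neighbouring loci are not independent.

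Across the genome, peaks gathered at gene ends and were wider there. Gene ends held 20419 peaks, 23.4% of the set (95% CI 23.1 to 23.7), against a mean of 8.82% for randomly placed peaks, a ratio of 2.66. Regions between genes held 29.1% of peaks against 47.1%, and the remainder lay inside protein-coding genes (41.7% against 37.4%) or only inside other genes (5.84% against 6.65%). Of protein-coding genes, 67.3% (95% CI 66.6 to 67.9) had a peak at either end and 14.8% at both, against 17.6% and 1.66% for randomly placed peaks. Long non-coding RNA genes had one in 43.9% and pseudogenes in 5.88%.

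Gene-end peaks had a median width of 1406 bp and distal peaks one of 488 bp. The difference of 918 bp gave p = 1e-05, the smallest that 100000 resamples of the permutation test allow. With peaks split by width into 10 classes of equal size, the share at gene ends was 7.80% in the narrowest class and 69.1% in the widest. Wide peaks meet a window more often by chance, and randomly placed peaks gave 6.63% and 14.2% in these classes. By peak midpoint, the shares were 7.54% and 54.4% and the difference of medians was 882 bp (permutation test, p = 1e-05). Peaks under 20 bp numbered 1405, or 1.61% of the set.

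**Figure D3:**
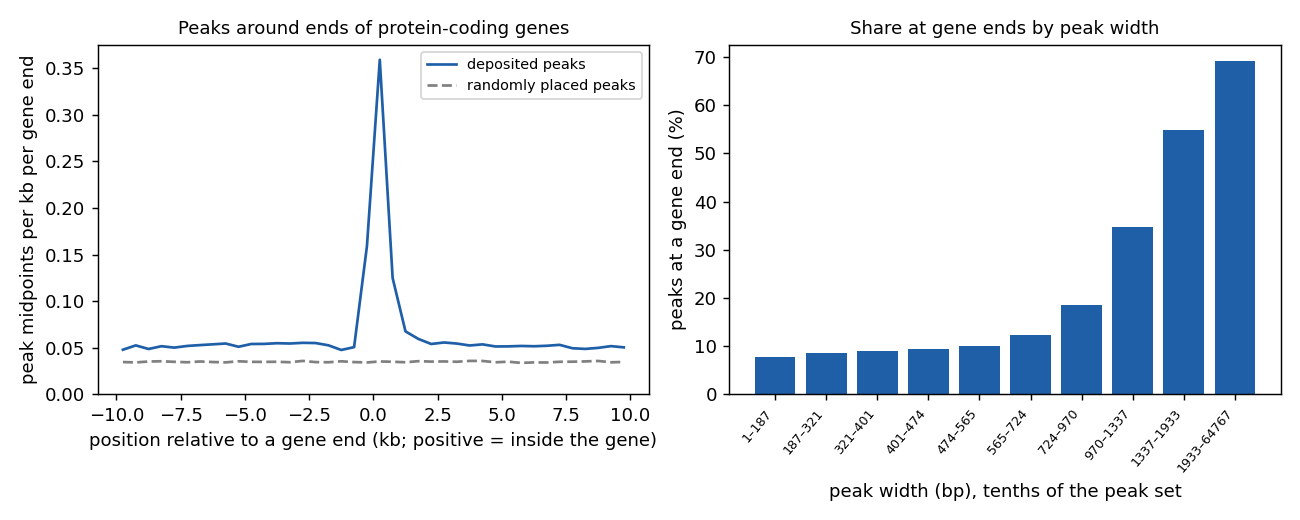
Left, peak midpoints per kb per gene end within 10 kb of the ends of protein-coding genes, positive positions lying inside the gene, for the deposited peaks and for randomly placed ones. The deposited peaks reached 0.359 per kb just inside gene ends, where random placement gave 0.0353. Right, percentage of peaks at a gene end in each of 10 classes of peak width in bp, from 7.80% to 69.1%.

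Chromosome X held fewer peaks than any autosome. Its 1605 peaks amounted to 9.58 per Mb against 35.6 over the autosomes, a ratio of 0.269, and single autosomes ranged from 28.3 per Mb on chromosome 14 to 48.7 on chromosome 11. A gene-end peak was present at 48.2% of X-linked protein-coding genes, among them the housekeeping gene Hprt, picked after its values were seen. The lowest autosome, chromosome 7, had 56% of genes with one. Chromosome Y held 16 peaks, and those at the single-copy genes Kdm5d, Eif2s3y, Uty and Ddx3y, chosen after their values were seen, were 173 to 696 bp wide. Sex and number of embryos are not stated in the labels, and no test was made across chromosomes.

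**Figure D4:**
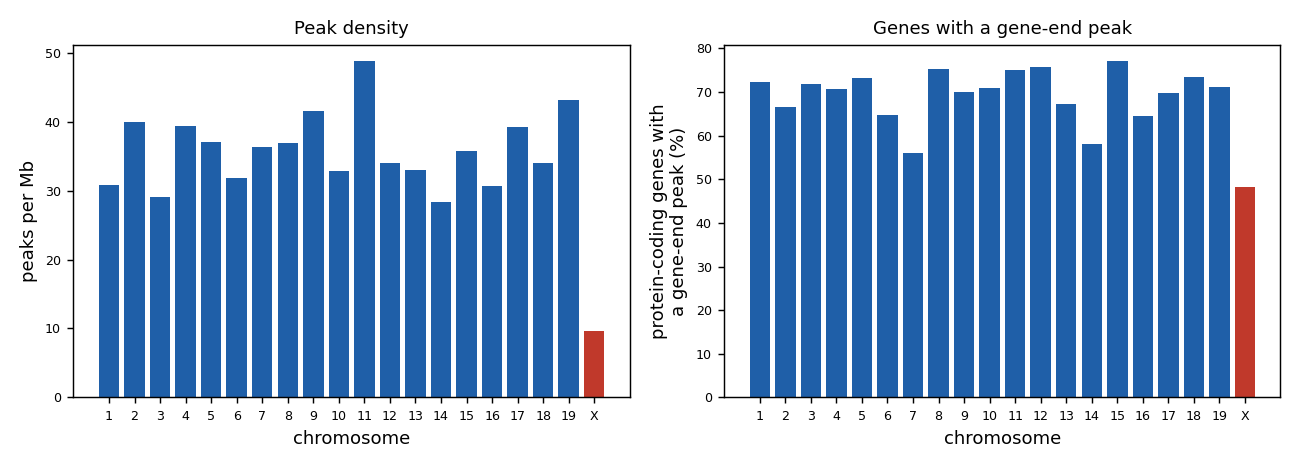
Peaks per Mb of chromosome span (left) and percentage of protein-coding genes with a gene-end peak (right) for the autosomes (blue) and chromosome X (red). X had 9.58 peaks per Mb and 48.2% of genes, both below the value of every autosome.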

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

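Tests on broad peaks and the alternatives of accessible length, counted gene-end peaks, matching on neighbours, 50 length classes, 1 member per 200 kb, kept scaffold genes, widths by peak midpoint and X density of gene-end peaks only were chosen after the data had been seen. The share of peaks at gene ends, 23.4% as reported, was 20.5% with a window of 500 bp, 31.5% with 2500 bp, 20.2% by peak midpoint, 17.4% with protein-coding genes only and 37.9% with peaks wider than the median. The share of protein-coding genes with a gene-end peak, 67.3%, was 64.8% with 500 bp, 71.4% with 2500 bp and 64.0% with peaks wider than the median. Window size and the genes or peaks counted set these shares by construction. The X to autosome ratio, 0.269 as reported, was 0.233 without gene-end peaks and 0.389 with gene-end peaks only, and the cause was not tested. With each peak given to its nearest gene end, 23 listed genes in place of 15 were among the 200 richest loci, and the cause was not tested. With 1 member per 200 kb, no list in place of 1 lay below the range for broad peaks, and the Hox list fell from above the range to a ratio of 0, since thinning left 4 Hox genes and 169 olfactory receptor genes.

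The gene-end and distal widths kept their difference under both windows and by peak midpoint, and the number of lists above the range of distal peaks stayed between 5 and 9 in place of 7. Over all lists and alternatives, 257 values kept their call, 17 lost the call, 12 gained one and 1, the Hox list for broad peaks, fell to the other side of a ratio of 1 but inside the range. Keeping scaffold genes changed no call on distal peaks and was not run for the gene-end and broad-peak lists. No value could be given for olfactory receptor genes among random lists of genes with a gene-end peak, because too few such genes are as short. The motif alternatives were not run. No paired analysis was possible because there is 1 group, and leaving out a library was not possible because the peak list does not separate the libraries. Depth is unknown, so a locus without a peak can be closed or too thinly sequenced.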

Other observations

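The gene families, the comparison with factors of other organs, the Fisher's exact tests on broad peaks and without olfactory receptor genes, the test on copies of Cwc22 and the genes named here were chosen after the data had been seen.

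Gene families differed in distal peaks per locus, and families of synaptic function lay on both sides of the range of random lists. Of 25 families examined, the teneurins, adhesion proteins of neuronal wiring, had 3.93 times as many distal peaks per locus as random lists of similar length, the nuclear factor I genes 3.20 times, the neurexins and neuroligins 2.71 times and the Dlx genes 2.57 times, all above the 99 percentile. Sox genes had 2.18 times as many, all 19 had a gene-end peak, and 10 of 19 had a peak of the broadest 1% within 1 kb. Semaphorin genes had 1.62 times as many and Wnt genes 1.79 times, and all 20 and all 19 had gene-end peaks. The 73 ribosomal protein genes, at 1.42 times, and the 103 histone genes, at 1.54 times, also lay above the range of random lists. Inside it lay the 18 ionotropic glutamate receptor genes at 1.31 times and the 22 Fgf genes at 0.968 times. Among other developmental families inside it were 13 Tbx (1.26 times), 5 Zic (1.59 times) and 4 Pou3f genes (1.52 times). The range was wider for small families, 0.75 to 6.5 distal peaks for Pou3f genes against 2.27 to 3.58 for ribosomal protein genes. A place inside or above the range therefore does not rank families of unlike size. GABA-A receptor genes had 0.359 times as many (percentile 0.01), although 13 of 17 had a gene-end peak, and several of them are neighbours. Vomeronasal receptor genes had 0.0447 times as many, cytochrome P450 genes 0.492 times and clustered protocadherin genes 0.580 times. The 367 numbered Zfp zinc finger genes had 0.686 times as many, although 83.1% had a gene-end peak, a share above the range. Thinning to 1 member per 200 kb was not done for the families. Clustered members, such as histone and protocadherin genes, share peaks, so percentiles of such families can be too extreme.

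The densest stretch of distal peaks in windows of 500 kb lay on chromosome 17 from 30500001 to 31000000, over part of Btbd9, Glo1 and Dnah8. It held 103 distal peaks, the next window 74 and the median window 12. Without olfactory receptor genes, 15 of 261 listed genes were among the 200 loci richest in distal peaks (odds ratio 7.03, two-sided Fisher's exact test, p = 2.06e-08). That list had given 0 of 1105, so leaving it out raised the share by construction. A peak of the broadest 1% lay within 1 kb of 12 of 20 striatal factors and 2 of 39 factors of other organs (odds ratio 27.8, two-sided Fisher's exact test, p = 7.25e-06). Of all peaks of the broadest 1%, 81.7% were at gene ends, so this says little about distal peaks. On chromosome Y, 10 of 16 peaks lay between 90726013 and 90813424.

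Striatal transcription factor loci held more distal peaks than random lists of similar gene length. After division by the mean of their length class, they exceeded 39 factors of blood, liver, muscle, heart and other organs 1.66 times (two-sided permutation test, p = 0.00123). The same class mean of 13.1 distal peaks divided Foxp1 (597405 bp) and Meis1 (139224 bp), so the longest genes were matched only coarsely. The comparison with other organs was not repeated with finer length classes. It therefore does not decide whether developmental factors of any organ have an equal excess. An excess shared with other organs, in part or as a whole, stays open. Hox genes reached 3.04 times the random mean (2.31 times with 1 member per 200 kb) and Fox genes 2.08 times. The 39 other factors reached 1.31 times (percentile 95.3, inside the range). The striatal loci stayed at the 100 percentile when random lists were also matched on neighbouring genes (2.59 times), and at the 100 percentile with 50 length classes (2.06 times). These values argue against sparse neighbours or residual length differences as the whole cause. With 10 length classes the ratio was 2.45, so residual length can account for a part of the excess. The hypothesis that these loci may carry more regulatory elements in this tissue stays open, since the design has no second tissue and this hypothesis was not tested.

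Chromosome X had 0.269 times the autosomal density of peaks. It held 1.67 peaks per protein-coding gene and single autosomes 2.56 to 5.86, which argues against gene content as the whole cause. Among 162 X-linked genes with a name stem of their own, 61.1% had a gene-end peak (95% CI 53.1 to 68.7), below the lowest autosome at 70.7%, which argues against multicopy families as the whole cause. Peaks at the Y genes Kdm5d, Eif2s3y, Uty and Ddx3y are in line with male nuclei being present, so fewer X copies per nucleus could lower the number of peaks called, as could X inactivation in any female nuclei, but the share of each sex is unknown and neither effect was measured. No biological explanation was tested.

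The widest peak, 64767 bp on chromosome 2 from 77887121 to 77951888, lay over Cwc22, a splicing factor gene, and peaks covered 99.01% of the gene span. Among 4 genes at least as long under other peaks of the 20 widest the highest coverage was 24.4%, at Sfi1, but this excludes nothing, because the widest peak away from the locus, 26231 bp, is shorter than any of these genes. Close by lay a peak of 25662 bp, from 77970103 to 77995765, over no annotated gene, and peaks of 13840, 4626 and 2030 bp. The peak of 13840 bp, from 77872638 to 77886478, also reached into Cwc22. Extra copies of the locus in C57BL/6J or CD1 embryos and a broad regulatory domain, both candidate explanations, cannot be told apart, because the peak list holds no read depth and the 99.01% coverage bears on both. No other explanation was tested.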
